A study of Mus musculus with 10 samples.

How the data were processed

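The data are chromatin immunoprecipitation sequencing (ChIP-seq) peak lists from mouse ES-E14TG2a embryonic stem (ES) cells and primary mouse embryonic fibroblasts (MEFs). Antibodies to the RNA polymerase III (Pol III) subunits POLR3C, POLR3G and POLR3GL and an N-20 antibody to RNA polymerase II (Pol II) were used in each cell type, with 1 library per antibody and cell type. Peak lists of the 8 immunoprecipitated libraries were used. The 2 input libraries were not analysed here. Per the labels' protocols, cells were fixed at 80% confluence, chromatin was sonicated to fragments averaging 200 to 700 bp, and about 10 µg of antibody was used. MEFs came from embryonic day 12.5 embryos and were used after 3 to 5 passages.

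CASAVA 1.8, Bowtie, SAMtools and HOMER are named in the submitters' processing notes, with the mouse build mm9. Calling thresholds, the control used for calling and the read depth of each library are not given in the sources used here. Each list has a chromosome, a start, an end, a peak name and 1 score, without a header line. The 6 Pol III lists give peaks of 1 fixed width per list, and their deposited score is a whole number whose scale is not stated. The 2 Pol II lists give peaks of variable width named as MACS peaks, and their deposited score has 2 decimals, a minimum of 50 and no stated scale. Scores were used to rank, split and correlate peaks and were not compared in size between lists. There is 1 list per library, and whether samples were pooled for calling is not given in the sources used here. Starts were read as 0-based, as in the BED layout, and all positions are printed 1-based on mm9. The gene table at hand is for another build, GRCm38. No gene name or annotation (exon, intron or UTR) was therefore attached to any peak, and loci are named by mm9 position. The planned tests by gene class and of ES cell, fibroblast and housekeeping gene lists need an mm9 annotation and were not run.

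Peaks of list A were counted as overlapping list B when they shared at least 1 bp. Shares have exact Clopper-Pearson 95% intervals. These cover counting error over peaks only, because peaks of 1 library are not replicates. The chance overlap came from 1000 random placements of list A within its own chromosomes (100 for Pol II against Pol II), between the first and the last base covered by any list. Permutation p-values are one-sided, and the smallest they can give is 0.001 (0.0099 for 100 placements). They were adjusted by the Benjamini-Hochberg method over the 18 directed comparisons between Pol III lists. The 6 Pol III lists were merged at 1 bp of overlap into loci, and a locus was scored as called by a list when it held a peak of it. Calls of pairs of lists on the same loci were compared by two-sided exact McNemar tests, adjusted over 8 tests. Such a test asks whether 1 list calls more loci than the other, so it follows the lengths of the lists. Shares were compared by two-sided Fisher's exact tests. Between cell types this test ignores that many loci are the same, such as the 246 called by POLR3C in both. Score correlations are across shared loci, with 100000 permutations, adjusted over 6 pairs. Loci at most 200 kb apart were joined into clusters, and clusters of 8 or more loci are reported. Comparisons of median scores between peaks with and without a partner (two-sided, 100000 permutations, adjusted over 6), the split by score quartile, the clusters and their comparison with Pol II (adjusted over 4), the Fisher's exact tests between cell types, and the comparisons on chromosomes 6 and 13 were chosen after seeing the data. For chromosome 13, POLR3G calls were shuffled within 10 score classes, and the interval of a difference between shares is Newcombe's. With 1 library per group no replicate error exists, and every p-value compares lists, not conditions.

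The rule for named loci, set before the data were examined, took the 5 highest-scored loci of each Pol III list and every locus of a list of 10 peaks or fewer, of which there were none. It also took up to 10 loci called by 2 or more lists in one cell type and by none in the other, up to 10 loci per cell type with POLR3G or POLR3GL but no POLR3C, and the 5 highest-scored Pol II peaks per cell type. The parts of the rule that need gene names could not be applied. Alternatives set before the data were examined were an overlap of at least 50% of the shorter peak, peaks widened by 500 bp on each side, only peaks at or above each list's median score, removal of chromosomes M and Y, placement over all chromosomes, Pol II windows of 1 and 5 kb, merging of peaks within a list, log2 scores, and removal of the 2 loci with the most extreme score. Alternatives added after seeing the data were rotation of all peaks of a chromosome by 1 random distance, shifts of each locus by up to 50 kb, removal of the POLR3G list of ES cells and removal of loci called by 1 list.

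Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. On the deposited lists the overlap counts equalled those of bedtools 2.31.1 in 56 of 56 directed pairs. On simulated data modelled on the MEF POLR3GL list (264 peaks), at least the planted number of overlaps was recovered in 3 of 3 lists, and the permutation test called 6 of 200 pairs of random lists at a threshold of 0.05. The exact McNemar test called 14 of 500 simulations without a difference. Simulated peaks were placed, and simulated calls drawn, independently of each other. The simulations check the code and do not give error rates for clustered loci or for lists with related calls.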

Results

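The series mapped Pol III and Pol II in ES-E14TG2a cells, an established male mouse embryonic stem cell line, and in primary MEFs. Pol III transcribes tRNA genes, 5S rRNA genes and other short non-coding RNA genes. POLR3C is a subunit of a subcomplex of Pol III that also holds either POLR3G or POLR3GL, 2 paralogous proteins, so the design sets the sites of the paralogs side by side in each cell type. The lists for ES cells held 317 POLR3C, 13 POLR3G and 243 POLR3GL peaks, and those for MEFs held 275 POLR3C, 177 POLR3G and 264 POLR3GL peaks. The Pol II lists held 32345 peaks in ES cells and 13306 in MEFs. Pol III peaks were 142 to 224 bp wide, with 1 width per list, while Pol II peaks had a median width of 955 bp in ES cells and 1087 bp in MEFs. Each value comes from 1 library, the read depth behind the lists is unknown, and differences in the length of lists have no replicate check.

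The Pol III peaks were strongly clustered in the genome. The 6 lists merged into 389 loci on 21 chromosomes, and 101 of these loci lay on chromosome 13, followed by 46 on chromosome 11 and 30 on chromosome 3. On chromosome 13, 99 of the 101 loci fell into 3 clusters within 2.37 Mb, from position 21252621 to 23622399. In mouse, a large group of tRNA genes on chromosome 13 is known, but no gene was assigned to these peaks. The cluster with the most loci, at chromosome 13 from 23362220 to 23622399, held 40 loci, of which 37 were called by POLR3C in ES cells, 34 by POLR3C in MEFs, 33 by POLR3GL in ES cells and 36 by POLR3GL in MEFs. The 2 clusters next in number on this chromosome held 34 loci (21802402 to 22142702) and 25 loci (21252621 to 21418704). Clusters of 17 loci each lay on chromosome 3 from 96125868 to 96305554 and on chromosome 11 from 68850440 to 68938871. Together, 9 clusters of at least 8 loci held 168 of the 389 loci, or 43.2%, and none of the 13 POLR3G peaks of ES cells lay in them.

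**Figure D1:**
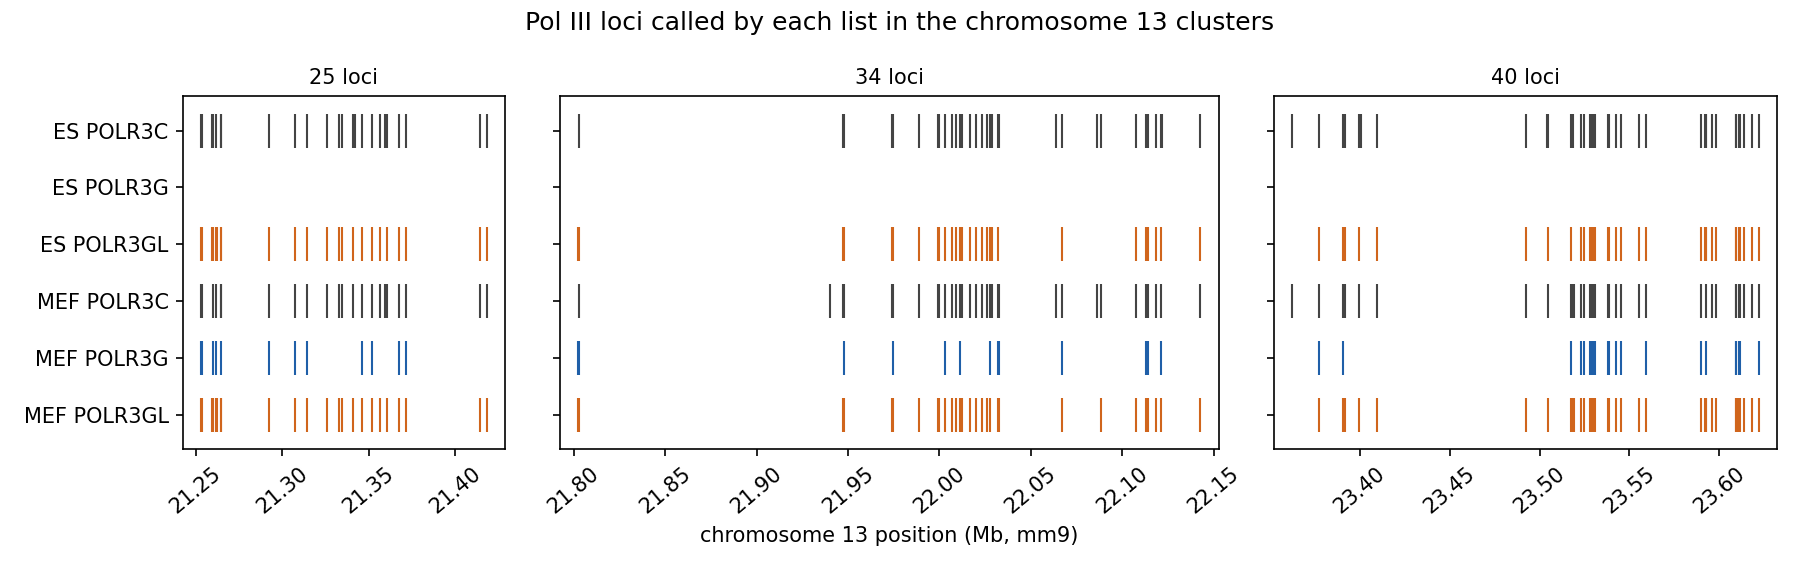
Loci called by each Pol III list (rows, 1 tick per locus) in the 3 clusters of chromosome 13, by position in Mb on mm9. The panels are drawn to approximately the same scale. POLR3C and POLR3GL of both cell types mark nearly the same positions, MEF POLR3G marks 46 of the 99 loci, and the ES POLR3G row is empty.

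Within MEFs, the 3 subunits occupied largely the same sites. POLR3GL peaks overlapped POLR3C peaks in 237 of 264 cases (89.8%, 95% interval 85.5 to 93.2%), and POLR3G peaks overlapped POLR3C peaks in 161 of 177 cases (91.0%, 85.7 to 94.7%). Of the 177 POLR3G peaks, 172 overlapped a POLR3GL peak (97.2%, 93.5 to 99.1%). Random placement gave at most 1 overlapping peak in any of these comparisons (permutation p = 0.001, the smallest possible, adjusted p = 0.0013). The reverse shares were lower for POLR3G, since only 65.2% (59.1 to 70.9%) of POLR3GL peaks and 58.5% (52.5 to 64.4%) of POLR3C peaks carried a POLR3G peak. On the same loci, 91 were called by POLR3GL and not by POLR3G and 4 by POLR3G and not by POLR3GL (exact McNemar test, adjusted p = 4.48e-22). List lengths bound these shares and set this imbalance, with 177 POLR3G peaks against 264 POLR3GL and 275 POLR3C peaks. Each list comes from 1 library of unknown depth, so a missing POLR3G call does not show that POLR3G is absent. In MEFs 38 loci were called by POLR3C and not by POLR3GL, and 27 by POLR3GL and not by POLR3C, a difference that the exact McNemar test did not separate from an even split (adjusted p = 0.21), although with peaks widened by 500 bp it did (difference of 30 loci, exact p = 1.38e-06, unadjusted).

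The sites at which MEF POLR3G was called had higher scores for the other subunits, in comparisons chosen after seeing the data. POLR3GL peaks with a POLR3G peak had a median score of 57 against 30 for those without (permutation test of medians, adjusted p = 1e-05, the smallest possible). Among the 66 POLR3GL peaks of the lowest score quartile, 6 (9.09%, 3.41 to 18.7%) carried POLR3G, and the share was 60.6%, 93.9% and 97.0% in the quartiles above it. Likewise, POLR3C peaks with POLR3G had a median score of 236 against 146 for those without (permutation test, adjusted p = 1e-05). Whether sites of low score lack POLR3G or only fell below its calling threshold cannot be told apart, because threshold and depth are unknown. Across loci, which are not independent replicates, POLR3GL and POLR3G scores were correlated (173 loci, Pearson r = 0.71, Spearman rho = 0.73), and so were POLR3C and POLR3GL (237 loci, r = 0.84, rho = 0.85) and POLR3C and POLR3G (161 loci, r = 0.52, rho = 0.50). Each of these had a permutation p of 1e-05, the smallest possible, raw and adjusted over 6 pairs. The locus at chromosome 7 from 127978905 to 127979128 had the highest score of both the POLR3G list (46) and the POLR3GL list (100) of MEFs and a POLR3C score of 304. The highest MEF POLR3C score (319) lay at chromosome 11 from 106874103 to 106874340, where POLR3G scored 39 and POLR3GL 86. It was followed by chromosome 14 from 51709099 to 51709325, with 314 for POLR3C, 29 for POLR3G and 91 for POLR3GL. The locus at chromosome 18 from 36961452 to 36961675 scored 302 for POLR3C, 37 for POLR3G and 77 for POLR3GL in MEFs, and in ES cells it was called by POLR3C (1248) and not by POLR3GL.

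**Figure D2:**
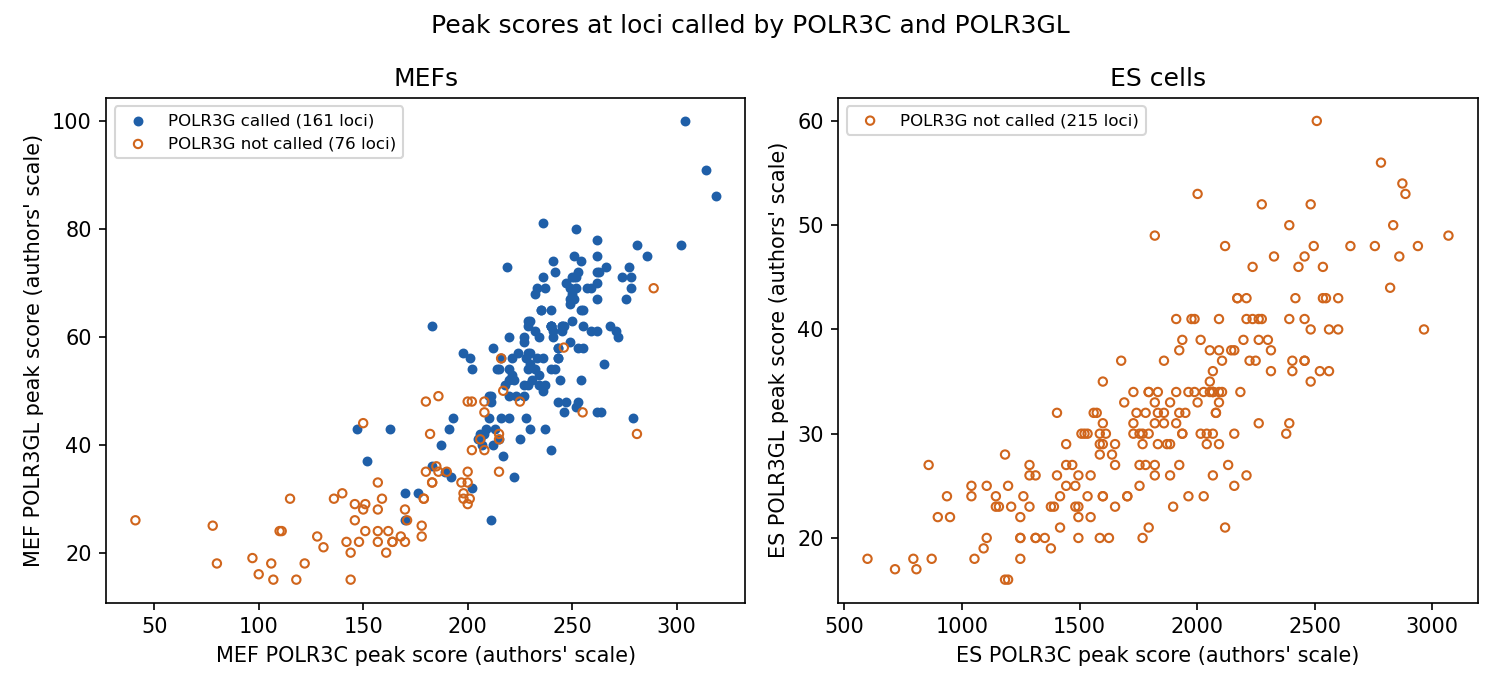
Scores of loci called by both POLR3C (x axis) and POLR3GL (y axis) in MEFs (left) and ES cells (right), on the authors' unstated scales; 1 point per locus, filled where POLR3G was also called. In MEFs the loci without POLR3G lie mainly at low scores, and in ES cells none of the 215 loci has a POLR3G call.

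In ES cells, POLR3C and POLR3GL also shared most sites, but the POLR3G list did not contain them. Of 243 POLR3GL peaks, 215 overlapped a POLR3C peak (88.5%, 83.8 to 92.2%, permutation p = 0.001, adjusted p = 0.0013), and 67.8% (62.4 to 72.9%) of POLR3C peaks overlapped POLR3GL. In ES cells 102 loci were called by POLR3C and not by POLR3GL, and 28 by POLR3GL and not by POLR3C (exact McNemar test, adjusted p = 7.08e-11). POLR3C peaks without POLR3GL had a median score of 448.5 against 1885 for those with it (permutation test, adjusted p = 1e-05). Scores of the 215 shared loci were correlated (r = 0.81, rho = 0.83, permutation p = 1e-05, the smallest possible). None of the 13 POLR3G peaks overlapped a POLR3C peak, and 0 of 317 POLR3C peaks carried POLR3G (upper 95% bound 1.16%). The names of the 13 peaks were numbered without a gap, but whether they are the whole list for this library is not given in the sources used here, and every value of ES POLR3G rests on it. Instead, 6 of the 13 lay on chromosome Y and 4 on chromosome X, and 3 on autosomes. Of the 13, 8 overlapped a POLR3GL peak of ES cells (61.5%, 31.6 to 86.1%, permutation p = 0.001, adjusted p = 0.0013). The highest POLR3G score (102) lay at chromosome Y from 2876328 to 2876498, where POLR3GL scored 99, its own highest score. The next (88) lay at chromosome Y from 2782188 to 2782346, where POLR3GL scored 86. At chromosome X from 73844357 to 73844510 POLR3G scored 40 and POLR3GL 45. None of these 3 sites was called by POLR3C in either cell type. Of the 12 POLR3GL peaks of ES cells on chromosomes X or Y, 1 overlapped a POLR3C peak. At the other 5 shared sites POLR3GL scored 16 to 24, and the 5 POLR3G peaks without POLR3GL included chromosome Y from 2796320 to 2796471 (33). Of the 13 POLR3G peaks, 3 lay in Pol II peaks of MEFs and 0 in Pol II peaks of ES cells. The ES POLR3C list led with chromosome 11 from 106874103 to 106874340 (3069), which also led the MEF POLR3C list, and chromosome 8 from 113586346 to 113586603 (2965). Apart from the sites on chromosome Y, the POLR3GL list of ES cells led with chromosome 13 from 23558877 to 23559138 (60) and chromosome 6 from 86353766 to 86353990 (56).

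**Figure D3:**
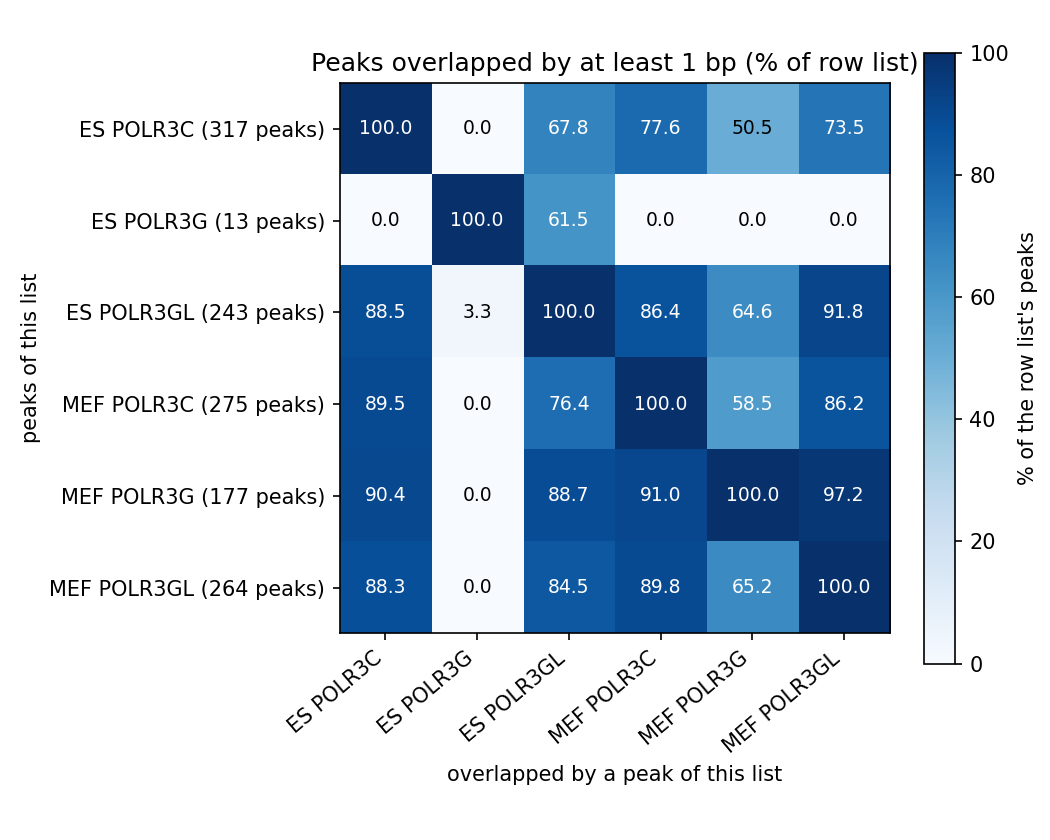
Percentage of the peaks of each Pol III list (rows, with the number of peaks) that share at least 1 bp with a peak of another list (columns). All pairs of lists other than ES POLR3G overlap, at 50.5% to 97.2% of peaks, and ES POLR3G overlaps only ES POLR3GL.

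Between ES cells and MEFs, the POLR3C and POLR3GL sites were mostly the same. Of the 275 MEF POLR3C peaks, 246 overlapped an ES POLR3C peak (89.5%, 85.2 to 92.8%), and of the 243 ES POLR3GL peaks, 223 overlapped a MEF POLR3GL peak (91.8%, 87.6 to 94.9%). The reverse shares were 77.6% (72.6 to 82.1%) of ES POLR3C peaks and 84.5% (79.5 to 88.6%) of MEF POLR3GL peaks (permutation p = 0.001 and adjusted p = 0.0013 for all 4). None of the 177 POLR3G peaks of MEFs overlapped one of the 13 in ES cells. Scores at shared loci were correlated for POLR3C (246 loci, r = 0.68, rho = 0.65) and POLR3GL (224 loci, r = 0.57, rho = 0.58; permutation p = 1e-05 for each). POLR3C called 71 loci in ES cells only and 29 in MEFs only (exact McNemar test, adjusted p = 4.29e-05). This imbalance is that of the list lengths, 317 and 275 peaks from 1 library each of unknown depth. POLR3C peaks without a partner in the other cell type had low scores, with medians of 377 against 1761.5 in ES cells and 78 against 218.5 in MEFs (permutation tests, adjusted p = 1e-05). POLR3GL called 19 loci in ES cells only and 40 in MEFs only (exact McNemar test, adjusted p = 0.0099). This difference did not hold with peaks widened by 500 bp (exact p = 0.14) or above the median scores, where the difference turned to 1 locus more in ES cells (exact p = 1).

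Of the 389 loci, 267 were called in both cell types, and 146 were called by all 5 lists other than ES POLR3G. A further 83 were called in ES cells only and 39 in MEFs only. Of the 83, 62 were called by POLR3C alone. Few of the loci called in 1 cell type only were called by more than 1 list. There were 9 such loci in ES cells. Of these, 8 were the sites of POLR3G and POLR3GL already described, which had no POLR3C peak and are not known to mark Pol III. No MEF list had a peak on chromosome Y, so the sites there do not show a difference between cell types. The remaining locus lay at chromosome 3 from 96138417 to 96138659, with scores of 1092 for POLR3C and 19 for POLR3GL. In MEFs there were 11 loci called by 2 or more lists and by none in ES cells, of which 4 lay within 500 bp of a peak of ES cells. The clearest of the other 7 was at chromosome 1 from 172974994 to 172975217, which scored 262 for POLR3C, 35 for POLR3G and 75 for POLR3GL in MEFs, and whose nearest peak in ES cells was 6143 bp away. Neighbouring loci at chromosome 8 from 113154363 to 113154586 and from 113155075 to 113155301 were called by POLR3C (142 and 122) and POLR3GL (22 and 18) in MEFs, and the nearest peak of ES cells was 366736 bp away from the second. A POLR3G or POLR3GL peak without POLR3C occurred at 33 loci in ES cells and 31 in MEFs. A POLR3C peak lay within 500 bp of 14 and 23 of them, respectively, so that part of these loci are neighbouring peaks that do not touch. For example, the locus at chromosome 14 from 51684450 to 51684607 scored 36 for POLR3G and 65 for POLR3GL in MEFs and 36 for POLR3GL in ES cells, and a POLR3C peak lay 202 bp away in MEFs and 203 bp away in ES cells.

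Pol II peaks overlapped a minority of the Pol III loci, more than by chance. In ES cells, 110 of 350 loci overlapped an ES Pol II peak (31.4%, 26.6 to 36.6%), 15.1-fold above random placement in the chromosome (2.08%, permutation p = 0.001). In MEFs, 93 of 306 loci overlapped a MEF Pol II peak (30.4%, 25.3 to 35.9%), 32.6-fold above random placement (0.933%, permutation p = 0.001). Shifting each locus by up to 50 kb instead, an alternative chosen after seeing the data that keeps its neighbourhood, gave 9.09% in ES cells and 4.17% in MEFs, or 3.46-fold and 7.29-fold enrichment (permutation p = 0.001 for both). The share depended on the setting. With the Pol III and the Pol II lists both cut at their median scores, it was 20.8% in ES cells and 21.5% in MEFs. Chance shares fell as well, to 1.46% and 0.579%, which left 14.3-fold and 37.1-fold enrichment. With Pol II within 5 kb the share was 50.6% and 51.6%, with enrichment over placement in the chromosome of 5.62-fold and 8.69-fold (permutation p = 0.001 for all 4). Over all 389 loci, 54 overlapped Pol II in ES cells only, 45 in MEFs only and 64 in both. The split of 54 against 45 was not separated from an even one (exact McNemar p = 0.42). The 45 include 8 ES POLR3C loci set apart below as repeat-like, which are not known to mark Pol III. Loci in clusters of 8 or more had Pol II less often than the other loci. The share was 15.5% (10.4 to 21.8%) of 168 against 41.6% (35.1 to 48.4%) of 221 for ES Pol II, and 11.9% (7.43 to 17.8%) against 40.3% (33.7 to 47.1%) for MEF Pol II (Fisher's exact test, adjusted p = 3.69e-08 and 1.5e-09). These tests count loci as independent, but the 168 clustered loci lie in only 9 clusters, so the p-values are likely too small. Single clusters differed widely. None of the 9 loci of the cluster on chromosome 1 from 172963955 to 173041676 overlapped a Pol II peak in either cell type, whereas MEF Pol II overlapped 5 of 9 loci (55.6%) of the cluster on chromosome 6 from 128710032 to 128793420 and 4 of 8 loci (50%) of that on chromosome 19 from 12076647 to 12086814. ES Pol II overlapped 2 of 9 and 1 of 8 loci of these clusters, respectively. The 146 loci called by 5 lists had Pol II more often than the rest, at 43.2% (35.0 to 51.6%) against 22.6% (17.5 to 28.4%) in ES cells and 39.0% (31.1 to 47.5%) against 21.4% (16.4 to 27.1%) in MEFs (Fisher's exact test, adjusted p = 4.84e-05 and 0.000278). The splits by cluster and by number of lists were chosen after seeing the data, and the tests of both take neighbouring loci as independent.

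**Figure D4:**
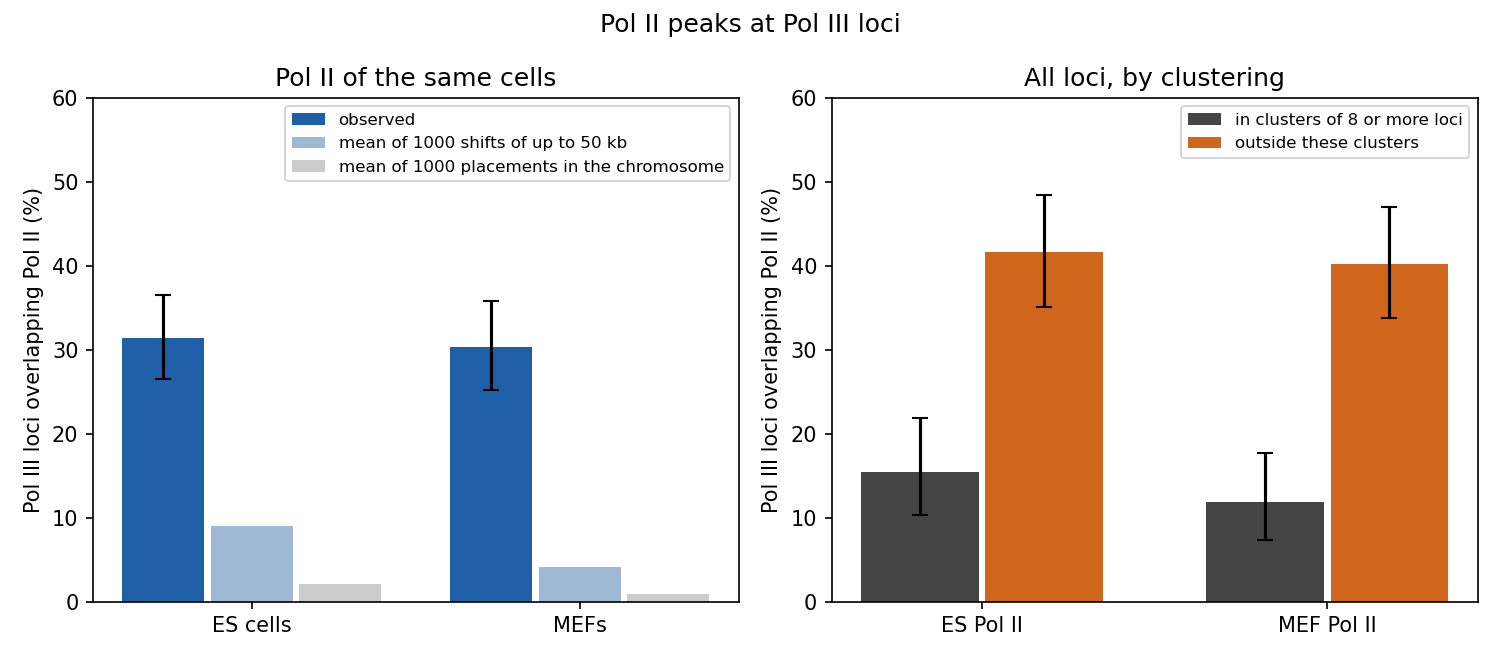
Percentage of Pol III loci that overlap a Pol II peak; bars start at 0 and error bars are exact 95% intervals over loci. Left, loci of each cell type against Pol II of the same cells (31.4% and 30.4%), beside the mean of 1000 local shifts and of 1000 placements in the chromosome; right, all 389 loci, in clusters of 8 or more loci and outside them.

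The Pol II lists of the 2 cell types differed in length, and peaks with higher scores were shared more often. Of the 13306 MEF peaks, 8265 overlapped an ES peak (62.1%, 61.3 to 62.9%), and of the 32345 ES peaks, 8733 overlapped a MEF peak (27.0%, 26.5 to 27.5%). Random placement gave at most 500 and 569 overlapping peaks (permutation p = 0.0099, the smallest possible for both). The share of MEF peaks found in ES cells was 36.6% in the lowest and 87.1% in the highest score quartile, and the share of ES peaks found in MEFs was 9.79% and 51.8%. The highest-scored peak of MEFs, at chromosome 4 from 116862046 to 116864860 (score 3100), and the 4 next to it in rank were all found in ES cells, among them chromosome 11 from 87256821 to 87258536 and chromosome 11 from 68886497 to 68888255. Of the 5 highest-scored peaks of ES cells only chromosome 1 from 155326916 to 155335137 (score 3200.71) was found in MEFs. The other 4, among them chromosome 2 from 71738080 to 71744411 (score 3233.06) and chromosome 12 from 40946039 to 40950809 (score 3228.29), had no MEF peak. None of these 10 peaks held a Pol III locus.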

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

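All tests in this part were chosen after the results were seen. The share of POLR3GL peaks with a POLR3G peak differed between the cell types. It was 3.29% (1.43 to 6.38%) in ES cells (2.10% without chromosomes M and Y) and 65.2% (59.1 to 70.9%) in MEFs, a difference of -61.9 percentage points that the length of the ES POLR3G list, 13 peaks, by itself makes large, so that no p-value is given. Whether the 13 peaks are the whole POLR3G list of ES cells is not given in the sources used here. POLR3G was called at 5 sites where POLR3GL scored 16 to 24. It was called at 0 of the 215 POLR3GL peaks with POLR3C (median score 31). This goes against lower depth alone only if POLR3G follows POLR3GL at both kinds of site, which was not tested. Of the 13 POLR3G peaks, 10 lay on chromosomes X or Y, where 1 of 12 POLR3GL peaks carried POLR3C. Whether the POLR3G peaks mark Pol III is therefore not known. A shallower POLR3G library, a failed immunoprecipitation and an absence of POLR3G from the POLR3C sites of ES cells cannot be told apart, because 1 library of this kind, of unknown depth, was made.

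The share of POLR3C peaks with a POLR3GL peak also differed, at 67.8% (62.4 to 72.9%) in ES cells and 86.2% (81.5 to 90.0%) in MEFs. The difference was -18.4 percentage points (Fisher's exact test, p = 1.3e-07). This test takes the peaks of the 2 cell types as separate, although 246 loci were in both POLR3C lists. List lengths also bound the shares, with 243 POLR3GL against 317 POLR3C peaks in ES cells and 264 against 275 in MEFs. The p-value therefore does not measure a change of POLR3GL at the same loci. With all lists cut at their median scores the difference was -7.11 points and no longer passed the test (Fisher's exact p = 0.16). The ES POLR3C list holds 62 loci that no other list calls. They may be peaks near the lowest score called, since their median score percentile within the list was 10.4 and only 1 of them lay above the median. Of the 62, 7 lay near the start of chromosome 9, 2 close together on chromosome 2 and 1 near the start of chromosome 12. These 10 were set apart as repeat-like, without a repeat annotation, and are not known to mark Pol III. Of the 10, 8 lay in Pol II peaks of MEFs and 0 in Pol II peaks of ES cells. This decides nothing on signal shared between antibodies, because these regions were picked after their values were seen. Over all 62 loci, 11 lay in peaks of MEF Pol II and not of ES Pol II (17.7%, 9.20 to 29.5%), so most were not called there. This comparison was set after its values were seen, and a missing call does not show missing signal. No conclusion on the source of the 62 loci is drawn from it. ES Pol II peaks held 17 of the 62 (27.4%, 16.9 to 40.2%), beside 31.4% of all ES loci, and occupancy by POLR3C without POLR3GL stays open and was not tested.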

How the results depend on the processing

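Rotation, local shifts, removal of the ES POLR3G list or of loci of 1 list, the differences in shares between cell types and the tests on chromosome 13 were chosen after the data were seen. Of 233 recomputed values of 50 results, 225 kept their direction and their side of the threshold or count range. This includes the 18 directed overlaps of Pol III lists with chance, under each overlap, placement and score alternative, and each of the 6 score correlations. Among the 18, the overlaps of ES POLR3G with ES POLR3C and with MEF POLR3G were 0 throughout and not above chance. Some of the 225 could hardly change, since placement alters only the chance value and merging within a list joined no peaks. Others counted as kept but moved in size. With peaks widened by 500 bp there were 306 loci instead of 389. Of these, 122 instead of 146 were called by all 5 lists other than ES POLR3G. The share of POLR3GL peaks with POLR3C ranged from 87.7% to 94.2% in ES cells and from 85.8% to 98.1% in MEFs. Shares between cell types were lower at or above the median scores, at 79.9% of MEF and 69.4% of ES peaks for POLR3C and 71.6% and 71.1% for POLR3GL. Every list is cut at its own median in that setting, so a peak also loses any partner below the other list's median. Lower shares there do not show that peaks of high score are shared less. Removal of chromosomes M and Y left 7 of the 13 POLR3G peaks of ES cells. At or above the median scores, the number of loci fell to 211 and that of loci called by 5 lists to 57, by construction. There, the loci called only by POLR3GL in ES cells less those only in MEFs turned from -21 to 1. The share of POLR3C peaks with POLR3GL differed by -7.11 percentage points between cell types (Fisher's exact p = 0.16). List lengths bound that share and changed too, to 135 POLR3GL and 160 POLR3C peaks in ES cells and 134 and 139 in MEFs. With peaks widened by 500 bp, the difference in POLR3GL loci between cell types was -11, and POLR3C called 30 loci more than POLR3GL in MEFs. The cause was not tested for these. At or above the median scores, the gap on chromosome 13 given under the other observations was -4.29 percentage points (Fisher's exact p = 0.82). No analysis paired by sample was possible because each group has 1 library, and calls were paired by locus only in the McNemar tests. Alternatives by gene class were not run for want of an mm9 annotation. Depth could not be given for any list. Of the 317 scores of ES POLR3C, 314 lay within 0.5 of a multiple of a step of about 13 that was fitted to them (7.69% for a step fixed beforehand), and the lowest was 20 steps. Were a step 1 read, the ES POLR3C library would be shallow, which bears on the loci it alone called, but the scaling is not stated.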

Other observations

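On chromosome 6, 9 loci between 128710032 and 128793420 formed 3 groups of 3 loci with a repeated layout. The first loci of the groups were 38.7 and 39.6 kb apart, and within the groups the second locus followed the first by 589, 643 and 594 bp and the third followed the second by 3467, 3541 and 4239 bp. POLR3C of both cell types and MEF POLR3GL called all 9 loci, ES POLR3GL called 7, and MEF POLR3G called 1. Median POLR3C scores in ES cells were 1313, 1040 and 1833 over the 3 groups, and median MEF POLR3GL scores were 30, 24 and 48. MEF Pol II overlapped 2, 2 and 1 loci of the groups, and ES Pol II overlapped 0, 0 and 2. This region was chosen after its values were seen.

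MEF POLR3G was called less often on chromosome 13 than elsewhere, a comparison chosen after seeing the data, with the tests of its explanations set down before their results. Of 88 POLR3GL peaks on chromosome 13, 51.1% (40.2 to 61.9%) carried POLR3G, against 72.2% (64.9 to 78.6%) of 176 peaks elsewhere (Fisher's exact p = 0.000977). With the POLR3GL and POLR3G lists both cut at their median scores the gap was -4.29 points and did not pass the test (Fisher's exact p = 0.82). That setting also drops POLR3G peaks of low score, so it does not give the same share among POLR3GL peaks of high score. With peaks widened by 500 bp the gap was -13.6 percentage points (-25.4 to -2.31, Fisher's exact p = 0.0253). By the rule set beforehand, a gap of more than 10 points goes against POLR3G peaks displaced from POLR3GL peaks as the cause. The interval, which that rule did not use, spans the bound, so displacement still cannot be told apart from other causes. Lower signal on chromosome 13 may account for the gap: the median POLR3GL score was 41 there against 54 elsewhere, and shuffling the POLR3G calls within deciles of POLR3GL score gave a gap of -21.1 points, beside -21.0 observed (permutation p = 1). Shuffling within deciles of POLR3C score, over 237 loci, gave -16.4 beside -21.8 points (permutation p = 0.29).

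MEF Pol II had 3 peaks on chromosome M and ES Pol II had 0. Between 2.9 and 3.1 Mb of chromosome 9, MEF Pol II had 11 peaks and ES POLR3C had 7, while none of the other 6 lists had any. Chromosome M and this part of chromosome 9 were set apart as repeat-like regions, without a repeat annotation. Whether the peaks there mark Pol II or Pol III, or signal from repeats, was not tested.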
